A study of Homo sapiens with 16 samples.

How the data were processed

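The series holds 16 arrays of cultured human endometrial cells: 4 groups of 4, made of epithelial cells (passage 1, on matrigel) and stromal fibroblasts (passage 2, on plastic), each untreated or exposed for 6 h to 1% seminal plasma (SP) pooled from 20 donors. Amplified, biotin-labelled RNA was hybridised to a whole-transcript Affymetrix array (Human Gene 1.0 ST). The series design also mentions a dose and time test of toxicity and a set comparing SP with fresh semen, which were not analysed here. The software that made the values is not given in the sources used here.

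The deposited values, a single table of 28869 rows by 16 arrays, are log values that had been centred per row on the median of the 16 arrays: the median of all 28869 rows was 0 within 1e-06. Array medians lay between -0.00783 and 0.0197. The widest row spanned 8.11 units, more than the 4.82 that a 16-bit scanner can give as log10, so log10 was excluded, whereas log2 and the natural logarithm were not told apart from the values. They were read as deposited log2 values, and every fold printed rests on that. Because of the centring the table no longer shows how bright a probe set was, so signal over background cannot be judged for any gene, and the number of arrays is what limits the precision that can be stated.

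Rows were joined to gene symbols through the platform's probe table. Of the 28869 rows, 19310 had 1 symbol (19279 also matched by gene ID to a RefSeq gene table of assembly GRCh38.p14, used for names and for which genes are Y-linked), 1752 had several symbols and 7807 had none. The files name no genome build, and no coordinates are given. Rows with 1 symbol were averaged per symbol, which gave 18377 genes, 685 of them with several rows. The design written before the data were examined had chosen the brightest row per gene, but in centred values the highest mean marks the row with the most rises rather than the brightest, so the mean of all rows was used and the highest-mean row became an alternative. For the same reason 2 planned filters on dim genes were not run.

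A model with 4 group means was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (12 residual degrees of freedom, 2.52 prior degrees of freedom). Tests were two-sided, with Benjamini-Hochberg adjustment over 18377 genes and a call at an adjusted p under 0.05. The contrasts were SP minus control in epithelial cells, SP minus control in stromal cells, the epithelial minus the stromal response, and control epithelial minus control stromal. Gene lists, 27 with 470 genes of which 436 were measured and the others not analysed here, were fixed before the data were examined. They were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Called with the preset value were 15 lists in epithelial and 10 in stromal cells, against 4 and 1 with an estimated correlation. Benjamini-Hochberg adjustment for lists ran over the 27 lists of a contrast. A separate count for each list was adjusted over the list alone. Overlaps of calls were tested with Fisher's exact test.

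The labels number the arrays of each group 1 to 4 without saying what a number shares. Deviations from group means, correlated over all genes, were 0.314, 0.333, 0.397 and 0.449 for same-numbered control and SP epithelial arrays and 0.337, 0.301, 0.418 and 0.285 for stromal arrays. All lie over 0.1, so the numbers were taken to pair arrays within a cell type. For 6 of the 8 numbers the control array correlated best with the SP array of its own number, whereas control epithelial array 1 correlated more with SP array 2 (0.455) and control epithelial array 2 more with SP array 1 (0.396). Across cell types same-numbered arrays correlated between -0.133 and 0.0703, so they were not taken to pair there. The paired fit, with the replicate number as a block within cell type, called 137 genes in epithelial cells against 87 without it, and its values are given wherever it changes a call.

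Genes were named by a rule written before the data were examined: for each SP contrast the 10 largest rises and 10 largest falls among called genes, for the other contrasts 6 each way, and from each list up to 4 called members per SP contrast with the largest change, or else the uncalled member with the largest change, given as a value. The rule named 140 genes. It skipped unnamed loci, small RNA genes, Y-linked genes and XIST. Genes outside the rule are marked as chosen after their values were seen.

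The pipeline was tested on simulated data with known changes over 18377 genes and with the residual spread of these arrays. In the simulated epithelial comparison 74.6%, 97% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 7.69% of calls false, and in the stromal one 77.6%, 91% and 100%, with 2.72% of calls false. The simulated noise was independent between genes and arrays, whereas deviations of the real arrays correlated as given above. These shares therefore test the code and need not hold for the real arrays. No pair of arrays was identical (0 pairs), and arrays of a group correlated between 0.626 and 0.889. Alternatives covered the variance prior, quantile normalization, centring of arrays, the replicate block within and across cell types, array weights, the 8 arrays of a comparison alone, all rows of the table, the probe rule, a threshold of 0.01, the list tests, and each array left out in turn. Added after seeing the data were fits without both stromal arrays numbered 1, without epithelial arrays numbered 3 and 4, and without those numbered 1 and 2.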

Results

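Transcript levels were measured on 16 Human Gene 1.0 ST arrays, 1 array per culture of human endometrial cells. Epithelial cells at passage 1 and stromal fibroblasts at passage 2 were left untreated or exposed for 6 h to 1% seminal plasma (SP), the cell-free fluid of semen, pooled from 20 donors. Each of the 4 groups (control epithelial, SP epithelial, control stromal, SP stromal) held 4 arrays, and this number limits the precision of every value. The labels do not say whether arrays of a group came from separate donors, so the p-values measure only the spread between these arrays. Changes are log2 differences of group means with their standard error, n = 4 arrays per group, and adjusted p is limma's value after Benjamini-Hochberg correction over 18377 genes. The base of the deposited logarithm is not stated, and log2 was assumed wherever a fold is printed.

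In epithelial cells, where the question was which transcripts 1% SP alters, metallothioneins rose the most. These small proteins bind zinc and copper. MT1M rose by 4.34 ± 0.33 (20.3-fold, adjusted p = 1.32e-05), MT1H by 3.64 ± 0.14 (12.5-fold, adjusted p = 2.05e-09), MT1F by 2.90 ± 0.18 (adjusted p = 1.46e-06) and MT1G by 2.87 ± 0.26 (adjusted p = 4.25e-05), each in 4 of 4 same-numbered pairs of arrays. SMOX, the spermine oxidase, rose by 1.63 ± 0.20 (adjusted p = 0.00123), and RIMKLB, a ligase that joins glutamate to other small acids, by 1.77 ± 0.26 (adjusted p = 0.00576). CSF3, the granulocyte growth factor G-CSF, rose by 1.56 ± 0.28 (adjusted p = 0.018). Among the falls, MAT2A, which makes the methyl donor S-adenosylmethionine, fell by 0.74 ± 0.11 (adjusted p = 0.00466), and the orphan receptor GPR160 fell by 0.74 ± 0.12 (adjusted p = 0.0113). The adhesion receptor ADGRF1 fell by 0.69 ± 0.12 (adjusted p = 0.0157), the chemokine CX3CL1 fell by 0.58 ± 0.10 (adjusted p = 0.02) and the zinc importer SLC39A10 fell by 0.75 ± 0.14 (adjusted p = 0.0317). All 5 falls were seen in 4 of 4 pairs.

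Several of these epithelial calls rested on few arrays. The CSF3 call was lost without control epithelial array 1 or 2 or SP epithelial array 3 (adjusted p up to 0.0788), and the ADGRF1 call without SP epithelial array 1 (adjusted p = 0.0567). The CX3CL1 call was lost without control epithelial array 1 or 2 or SP epithelial array 1, 3 or 4 (adjusted p up to 0.0801). The SLC39A10 call was lost without any 1 of the epithelial arrays except SP epithelial array 2, and without control stromal array 3 (adjusted p up to 0.107). With only the 8 epithelial arrays in the model, adjusted p was 0.103 for RIMKLB, 0.0502 for MAT2A, 0.163 for GPR160, 0.158 for ADGRF1, 0.0722 for CX3CL1 and 0.167 for CSF3. Leaving out epithelial arrays 1 and 2 of both groups gave 0.0824 for SMOX, 0.241 for MAT2A, 0.0959 for GPR160, 0.18 for ADGRF1 and 0.27 for CX3CL1, and adjusted p for SLC39A10 was 0.287 without them and 0.237 without arrays 3 and 4. Other falls among the 10 largest were those of CHST4, a sulfotransferase (-1.01, adjusted p = 0.0318), CYP1A1, a cytochrome P450 (-0.91, adjusted p = 0.0367), CLMN (-0.75, adjusted p = 0.0489), TMEM62 (-0.61, adjusted p = 0.0294) and SPA17 (-0.57, adjusted p = 0.0448). These calls were lost without 1 of several arrays. For CHST4 these were control epithelial arrays 2 to 4, SP epithelial arrays 1 and 2, control stromal array 3 and SP stromal arrays 1 and 4 (adjusted p up to 0.113), and for CYP1A1 control and SP epithelial array 1, control epithelial array 3, SP epithelial array 4 and all stromal arrays but control stromal array 1 (up to 0.107). For CLMN they were all but control epithelial array 1 (up to 0.161), for TMEM62 all epithelial arrays but SP epithelial array 3 (up to 0.106), and for SPA17 all but control epithelial array 4, SP epithelial array 4 and SP stromal array 3 (up to 0.13). With the replicate number as a block adjusted p was 0.0918 for CYP1A1 and 0.0619 for SPA17.

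Of 13 measured genes of the metallothionein and zinc list, 8 rose, 1 fell (SLC39A10) and 4 were not called (10 rose and 1 fell adjusted over the list alone). The list shifted upward against the other genes (mean 1.49, adjusted p = 8.71e-26, adjusted p = 0.0045 with an estimated correlation). The immediate early list, genes switched on within hours by growth and stress signals, had 3 of 23 members called, all rises (6 adjusted over the list alone). These were the nuclear receptors NR4A2 (1.18 ± 0.22, adjusted p = 0.0294) and NR4A1 (0.77, adjusted p = 0.0175) and the survival gene IER3 (0.76, adjusted p = 0.018), and the list mean was 0.36 (adjusted p = 1.03e-10, adjusted p = 0.0714 with an estimated correlation). The NR4A1 call was lost without control epithelial array 1 or 3 or SP epithelial array 1 (adjusted p up to 0.0651). The IER3 call was lost without control epithelial array 1 or 2 or SP epithelial array 1, 3 or 4 (adjusted p up to 0.0766), and the NR4A2 call without control epithelial array 1, 2 or 3 or SP epithelial array 2, 3 or 4 (adjusted p up to 0.105). The prostaglandin and cAMP list had 1 of 15 members called, the cAMP phosphodiesterase PDE4D (0.74, adjusted p = 0.0395), a call lost without any 1 array other than SP epithelial array 3 or 4 (adjusted p up to 0.139), and 5 rises adjusted over the list alone. Its mean was 0.40 (adjusted p = 1.34e-05, adjusted p = 0.0045 with an estimated correlation). The EGF family and growth factor list had 0 of 16 members called by limma (5 at an unadjusted p under 0.05, 2 adjusted over the list alone) and a mean of 0.51 (adjusted p = 1.34e-05, adjusted p = 0.013 with an estimated correlation).

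Among the next epithelial lists, no shift was called with an estimated correlation. Cytokines and chemokines had CSF3 as the only rise among 20 members (7 rises and 1 fall adjusted over the list alone), with a mean of 0.45 (adjusted p = 0.000283, adjusted p = 0.179 with an estimated correlation). In the NF-kB, TGF-beta, NRF2, cholesterol, interferon and hypoxia lists, limma called 0 members, while 4, 6, 3, 6, 13 and 7 members passed an unadjusted p under 0.05. Adjusted over the list alone, 2 NF-kB targets, 3 TGF-beta targets and 2 NRF2 genes were higher. NF-kB targets (mean 0.17, adjusted p = 0.00025, adjusted p = 0.121 with an estimated correlation), TGF-beta targets (mean 0.41, adjusted p = 0.000283, adjusted p = 0.164 with an estimated correlation) and the antioxidant NRF2 list (mean 0.22, adjusted p = 0.000289, adjusted p = 0.121 with an estimated correlation) shifted upward. INHBA, an activin subunit on the TGF-beta list, had a change of 2.37 ± 0.59 that was not called (adjusted p = 0.123), but was called with the replicate block (adjusted p = 0.00266). Its levels, relative to the median of all arrays, were -3.81, -3.73, -2.30 and -2.43 in control arrays 1 to 4 and -1.63, -2.09, 0.23 and 0.70 in the SP arrays. Genes of cholesterol synthesis shifted downward (mean -0.29, adjusted p = 1.02e-07, adjusted p = 0.121 with an estimated correlation, 5 falls adjusted over the list alone), with HMGCS1 at -0.70 (adjusted p = 0.311, adjusted p = 0.0205 with the block).

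The interferon and hypoxia shifts were carried by epithelial arrays 1 and 2. The interferon list had a mean change of -0.59 (adjusted p = 1.18e-09, adjusted p = 0.149 with an estimated correlation, 12 of 20 members lower adjusted over the list alone), and the antiviral gene IFIT1 stood at -1.33 ± 0.43 (adjusted p = 0.282). Its mean level was 0.88, 1.69, 1.21 and 0.72 in control arrays 1 to 4 and 0.17, 0.14, 1.16 and 0.65 in the SP arrays. Without arrays 1 and 2 the mean change was -0.06 (adjusted p = 0.618), and without arrays 3 and 4 it was -1.13. The hypoxia and glycolysis list had a mean change of 0.43 (adjusted p = 2.77e-08, adjusted p = 0.141 with an estimated correlation, 5 rises of 17 adjusted over the list alone), with NDRG1, a hypoxia-induced gene, at 0.94 (adjusted p = 0.0681). Without arrays 1 and 2 its mean change was 0.0028 and the test turned to the other direction (adjusted p = 0.51).

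On the processes that the series title names, migration, proliferation and viability, no list member was called in epithelial cells by limma. The migration and protease list had 0 of 21 members called by limma (1 at an unadjusted p under 0.05), a mean of 0.22 (adjusted p = 0.0457, adjusted p = 0.652 with an estimated correlation) and the protease MMP10 at 1.10 (adjusted p = 0.615; 0.56 without control epithelial array 2 and 0.63 without SP epithelial array 4). That shift was lost after quantile normalization (adjusted p = 0.121) and without control epithelial array 1 or 2, SP epithelial array 3 or 4 or SP stromal array 2, 3 or 4 (adjusted p up to 0.712, mean down to 0.051). The mitosis list had 0 of 21 called (1 at an unadjusted p under 0.05) and a mean of 0.12 (adjusted p = 0.0343, adjusted p = 0.655 with an estimated correlation), lost without control epithelial array 2 or 4 or SP epithelial array 2 (adjusted p up to 0.668, mean down to 0.017). It was carried by epithelial arrays 1 and 2, since its mean was -0.0042 without them (adjusted p = 0.953) and 0.24 without arrays 3 and 4. The S phase list, also with 0 called, had a mean of 0.03 and a median of -0.02 (adjusted p = 0.498), and was called without SP epithelial array 4 (adjusted p = 0.0405) and without arrays 3 and 4 (mean 0.13, adjusted p = 0.0342), while its mean was -0.07 without arrays 1 and 2. The apoptosis and survival list had 0 of 18 called (4 at an unadjusted p under 0.05, 2 rises and 1 fall adjusted over the list alone) and a mean of 0.07 (adjusted p = 0.0594). That test passed without control epithelial array 1, SP epithelial array 2 or control stromal array 1 or 2 (adjusted p down to 0.0222). It also passed after quantile normalization, with array weights, with the highest-mean row and without both stromal arrays 1. The mean was 0.15 without epithelial arrays 1 and 2 (adjusted p = 0.0123) and -0.0024 without arrays 3 and 4 (adjusted p = 0.815).

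No shift was called in epithelial cells for p53 targets (mean -0.04, adjusted p = 0.95), decidualization (0.14, adjusted p = 0.0905), heat shock (-0.07, adjusted p = 0.232), the unfolded protein response (-0.0012, adjusted p = 0.849), steroid receptors and glucocorticoid targets (0.06, adjusted p = 0.948) or receptors for SP components (-0.07, adjusted p = 0.0868). The decidualization shift was called without control epithelial array 4 (adjusted p = 0.0499). Without epithelial arrays 1 and 2, the unfolded protein list (mean 0.13, adjusted p = 0.0378) and the receptor list (-0.13, adjusted p = 0.0214) were called, and without arrays 3 and 4 these means were -0.13 and -0.02, neither called. Nor was one called for markers of leukocytes (0.04, median -0.00025, adjusted p = 0.814), endothelium (0.06, adjusted p = 0.75) or smooth muscle (0.03, adjusted p = 0.78). Of 15 epithelial markers, the transcription factor ELF3 rose (0.72, adjusted p = 0.0317), a call lost without any 1 array other than SP epithelial array 4, control stromal array 1 or 4 or SP stromal array 2 or 3 (adjusted p up to 0.104). The marker list did not shift (mean -0.07, adjusted p = 0.125), except without control epithelial array 4 (adjusted p = 0.0361). Stromal fibroblast markers had a mean change of 0.26 (adjusted p = 0.0486, adjusted p = 0.604 with an estimated correlation), a shift that was lost without any 1 array other than control epithelial array 3 or 4 or SP epithelial array 1 or 2 (adjusted p up to 0.755, mean 0.016 without control epithelial array 2) and that turned to -0.033 after quantile normalization (adjusted p = 0.836). The mean change was 0.05 without epithelial arrays 1 and 2 (adjusted p = 0.234) and 0.46 without arrays 3 and 4. Their mean level was -2.01, -2.36, -1.09 and -1.04 in control epithelial arrays 1 to 4 and -1.79, -1.65, -1.26 and -0.76 in the SP epithelial arrays.

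Limma called 87 of 18377 genes in epithelial cells, 60 higher and 27 lower with SP, and 55 of them changed at least 1.5-fold (47 higher, 8 lower). At an unadjusted p under 0.05 there were 1674. With the replicate number as a block 137 genes were called, 73 of them shared with the 87. The count was 49 without control epithelial array 2, 49 without SP epithelial array 1, 51 without control epithelial array 3 and 36 with only the 8 epithelial arrays, and the count at 1.5-fold was 35 without control epithelial array 2. Leaving out arrays 3 and 4 gave 228 genes and leaving out arrays 1 and 2 gave 46.

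**Figure D1:**
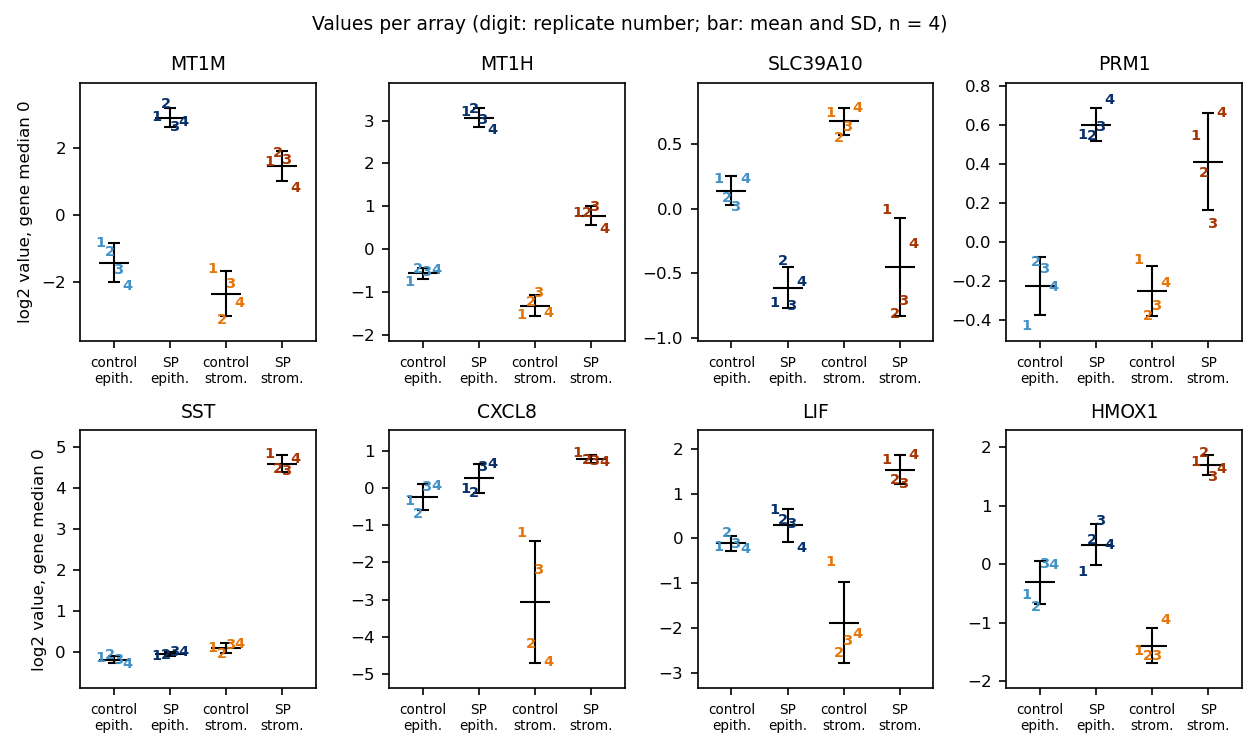
Levels of 8 genes on the 16 arrays (log2, relative to each gene's median over all arrays), by group, with digits marking the array number and bars showing mean ± SD, n = 4. MT1M and MT1H were higher with SP in every same-numbered pair of both cell types, whereas SST rose by 4.51 in stromal cells and had a change of 0.14 in epithelial cells.

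In stromal fibroblasts, asked the same question, the hormone gene SST (somatostatin) rose by 4.51 ± 0.09 (22.8-fold, adjusted p = 1.55e-13). The cytokines IL11 (3.90 ± 0.64, 14.9-fold, adjusted p = 0.000919), CXCL8, which attracts neutrophils (3.86 ± 0.56, adjusted p = 0.000369), and IL33 (3.44 ± 0.70, adjusted p = 0.00402) rose too. LIF, which is needed for implantation in mice, rose by 3.42 ± 0.34 (adjusted p = 2.08e-05). Other rises were those of HAS2, which makes hyaluronan (3.85 ± 0.39, adjusted p = 2.29e-05), and of the metallothionein MT1M (3.83 ± 0.33, adjusted p = 6.72e-06). The endothelin receptor EDNRB (3.46 ± 0.57, adjusted p = 0.000845), the EGF receptor ligand EREG (3.33 ± 0.50, adjusted p = 0.000465) and the cytokine receptor IL7R (3.31 ± 0.39, adjusted p = 8.59e-05) rose as well. The largest fall was that of DEPP1, a target of FOXO transcription factors (-3.33 ± 0.41, adjusted p = 0.000114). Next came the transcription cofactor LBH (-2.59 ± 0.17, adjusted p = 6.42e-07), the TNF receptor family member TNFRSF19 (-2.50 ± 0.39, adjusted p = 0.000565), the VEGF receptor KDR (-2.30 ± 0.20, adjusted p = 6.69e-06) and the serotonin receptor HTR2B (-2.23 ± 0.44, adjusted p = 0.00336). STMN2, which binds tubulin, stood at -2.23 ± 0.23 (adjusted p = 2.93e-05), ETV1 at -2.02, the keratin KRT19 at -2.0 and the transcriptional regulator CITED2 at -1.96 ± 0.14 (adjusted p = 1.86e-06). The iron exporter SLC40A1 stood at -1.98 ± 0.49 (adjusted p = 0.0134), a call lost with only the 8 stromal arrays (adjusted p = 0.0535).

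Inflammatory genes rose together in stromal cells. Of 20 cytokines and chemokines 11 rose and 9 were not called (13 rises adjusted over the list alone), with a mean of 1.64 (adjusted p = 1.03e-08, adjusted p = 0.106 with an estimated correlation). Of 14 NF-kB targets 11 rose and 3 were not called (12 rises adjusted over the list alone), with a mean of 0.87 (adjusted p = 5.37e-12, adjusted p = 0.0203 with an estimated correlation). Examples were the adhesion molecule ICAM1 (2.32 ± 0.27, adjusted p = 7.17e-05), the NF-kB subunit REL (1.67 ± 0.10, adjusted p = 6.42e-07) and the NF-kB inhibitors NFKBIA (1.62, adjusted p = 1.21e-05) and TNFAIP3 (1.32, adjusted p = 1e-05). Control stromal array 1 lay between the other controls and the SP arrays. On an axis from the other 3 controls at 0 to SP at 1, its median position was 0.46 over 1345 genes called without it, 0.41 over called cytokines and 0.15 over called NF-kB targets. The receptor list had 3 rises and 3 falls among 21 members, and no shift (mean -0.07, adjusted p = 0.387). The interleukin 1 receptor IL1R1 rose (1.44, adjusted p = 0.000178), and the toll-like receptor TLR4 fell (-1.40, adjusted p = 0.0127).

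Of 16 EGF family and other growth factors 5 rose in stromal cells (5 adjusted over the list alone) and 0 fell by limma, with 1 lower at an unadjusted p under 0.05. They included NRG1, a ligand of ERBB receptors (2.85, adjusted p = 0.000599), HGF (2.27, adjusted p = 0.000657) and FGF2 (2.08, adjusted p = 0.00704). The list mean was 0.85 (adjusted p = 0.0184, adjusted p = 0.106 with an estimated correlation), and control stromal array 1 lay at 0.32 over the called members. Of 23 immediate early genes 12 rose and 1 fell (13 and 1 adjusted over the list alone), with a mean of 0.65 (adjusted p = 3.45e-07, adjusted p = 0.106 with an estimated correlation) and array 1 at 0.52. Examples were NR4A2 (2.56 ± 0.22, adjusted p = 6.69e-06), the growth regulator MYC (1.56, adjusted p = 0.0033) and the MAPK feedback inhibitor SPRY2 (1.38, adjusted p = 0.00239). In the prostaglandin and cAMP list 5 of 15 rose and 1 fell, among them the prostaglandin synthases PTGS2 (2.75 ± 0.45, adjusted p = 0.000914) and PTGS1 (1.89, adjusted p = 0.0155, and 0.0514 without control stromal array 2). The fall was in the scaffold gene AKAP12 (-0.91, adjusted p = 0.0017). This list had a mean of 0.42 (adjusted p = 0.0633, adjusted p = 0.0441 with the replicate block), and it was called without SP epithelial array 4, control stromal array 2 or SP stromal array 3 (adjusted p down to 0.0353). TGF-beta targets moved both ways (2 rose and 2 fell of 19, mean 0.34, adjusted p = 0.296). KLF10 rose (1.03, adjusted p = 0.000299), the matrix gene CCN1 fell (-1.19, adjusted p = 0.00331), and INHBA stood at 1.52 (adjusted p = 0.109, adjusted p = 0.00261 with the block).

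For migration in stromal cells, 6 of 21 members of the migration and protease list rose and 1 fell (7 and 2 adjusted over the list alone). ITGB3, an integrin, rose by 1.20 (adjusted p = 0.0016), the matrix protein TNC by 1.75 (adjusted p = 0.0238), the integrin ITGA2 by 1.75 (adjusted p = 0.0248) and the plasminogen activator PLAU by 1.43 (adjusted p = 0.0183). The last 3 calls rested on few arrays. The TNC call was lost without control stromal array 2 or 3 or SP stromal array 1 (adjusted p up to 0.0823), and the PLAU call without control stromal array 2 or 4 (adjusted p up to 0.0665). The ITGA2 call was lost without control stromal array 2, 3 or 4 or SP stromal array 1 or 2 (adjusted p up to 0.0835). The list mean was 0.38 (adjusted p = 0.111), and the list was called without control stromal array 1 (adjusted p = 0.0238), which lay at 0.74 over the called members. For proliferation, 0 of 21 S phase genes were called by limma (3 at an unadjusted p under 0.05, mean 0.04, adjusted p = 0.772). RRM2 (0.47) and CDC6 (0.63, adjusted p = 0.0564) were called with the block (adjusted p = 0.0214 and 0.0209). CDC6 was also called after quantile normalization, with array weights and without control stromal array 3 or SP stromal array 4 (adjusted p down to 0.0135). Of 21 mitotic genes 1 fell, the kinesin KIF23 (-0.62, adjusted p = 0.0185), a call lost without control stromal array 3 or SP stromal array 1 or 4 (adjusted p up to 0.0587). The mitosis list mean was -0.13 (adjusted p = 0.162), and the list was called as lower without control stromal array 1 or SP stromal array 3 (adjusted p down to 0.0134). Of 17 p53 targets and cell cycle inhibitors 7 fell, 0 rose by limma (1 higher at an unadjusted p under 0.05) and 10 were not called (8 falls and 1 rise adjusted over the list alone). TP53INP1, which promotes cell death (-1.93 ± 0.20, adjusted p = 2.96e-05), the cyclin-dependent kinase inhibitor CDKN1B (-1.16 ± 0.15, adjusted p = 0.000187) and the p53 target ZMAT3 (-0.75, adjusted p = 0.000663) were among them. The list mean was -0.38 (adjusted p = 0.000601, adjusted p = 0.106 with an estimated correlation), with control stromal array 1 at 0.36. For viability, the apoptosis and survival list had 2 rises and 3 falls among 18 members and no shift (mean 0.0038, adjusted p = 0.97). The survival genes MCL1 (0.96, adjusted p = 2.1e-05) and BIRC2 (0.65, adjusted p = 0.000117) rose, and BCL2L1, another survival gene, fell (-0.72, adjusted p = 0.000133). BMF, which promotes apoptosis, fell too (-1.05, adjusted p = 0.000236).

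Stress genes rose in part. Of 13 metallothionein and zinc genes 10 rose and 1 fell (the same numbers adjusted over the list alone), with a mean of 1.18 (adjusted p = 2.18e-09, adjusted p = 0.106 with an estimated correlation) and control stromal array 1 at 0.31. MT1F rose by 2.52 (adjusted p = 1.79e-06), MT1H by 2.10 (4.3-fold, adjusted p = 6.42e-07) and MT1G by 2.06 (adjusted p = 0.000121), while SLC39A10 fell by 1.13 ± 0.14 (adjusted p = 0.000145). Of 14 NRF2 genes 4 rose (6 adjusted over the list alone), with a mean of 0.53 (adjusted p = 0.000719, adjusted p = 0.106 with an estimated correlation). The heme-degrading enzyme HMOX1 rose by 3.09 ± 0.20 (adjusted p = 6.42e-07) and GCLM, which makes glutathione, by 1.32 (adjusted p = 8.29e-05). Of 12 heat shock genes 4 rose and 1 fell (5 and 1 adjusted over the list alone). The mitochondrial chaperones HSPD1 (0.83, adjusted p = 1.82e-05) and HSPE1 (0.68, adjusted p = 0.000526) rose, and HSPB1 fell (-0.62, adjusted p = 0.00559). The heat shock shift (mean 0.13, adjusted p = 0.0358, adjusted p = 0.106 with an estimated correlation) was lost with the block (adjusted p = 0.144) and without control stromal array 3 or SP stromal array 1 or 2 (adjusted p up to 0.0607). Of 17 genes of the unfolded protein and amino acid response 5 rose (6 rises and 1 fall adjusted over the list alone), among them the chaperone cofactor SDF2L1 (0.68, adjusted p = 0.000658). That list had a mean of 0.10 (adjusted p = 0.1) and was called without control stromal array 4 or SP stromal array 3 (adjusted p down to 0.0328).

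Among other stromal lists, hypoxia and glycolysis had 5 rises and 2 falls of 17 and no shift (mean 0.27, adjusted p = 0.151). The vascular growth factor VEGFA (1.86 ± 0.18, adjusted p = 1.61e-05) and the glycolytic regulator PFKFB4 (1.86, adjusted p = 3.46e-05) rose. Decidualization had 3 rises of 14, SST, BMP2 (0.94, adjusted p = 0.0219) and CEBPB (0.33, adjusted p = 0.00637). Its shift was not called by camera (mean 0.25, adjusted p = 0.274) but was by fry (adjusted p = 9.11e-06). The BMP2 call was lost without control stromal array 2 or 4 or SP stromal array 1 or 4 (adjusted p up to 0.0674). Steroid receptors and glucocorticoid targets had 2 rises and 1 fall of 14 and no shift (mean 0.21, adjusted p = 0.602), with the glucocorticoid receptor NR3C1 at 1.37 (adjusted p = 8.69e-05). Smooth muscle and pericyte markers had 5 falls of 12 (5 adjusted over the list alone) and a mean of -0.43 (adjusted p = 0.00114, adjusted p = 0.106 with an estimated correlation), with the contractile gene CNN1 at -1.61 ± 0.17 (adjusted p = 3.81e-05). Cholesterol synthesis had 2 falls of 15 and a mean of -0.19 (adjusted p = 0.00903, adjusted p = 0.451 with an estimated correlation), a shift lost without SP stromal array 1 (adjusted p = 0.0578). The interferon list had 1 fall of 20, IFIT3 (-1.45 ± 0.29, adjusted p = 0.00308), and no shift (mean -0.19, adjusted p = 0.261). Endothelial markers had 2 falls of 12, KDR and TEK (-1.64, adjusted p = 0.000138), with a mean of -0.26 and a median of 0.07. Their shift was not called by camera (adjusted p = 0.627) but was by fry (adjusted p = 0.0491). No shift was called for markers of epithelium (1 rise and 1 fall of 15, mean -0.13, median 0.0032, adjusted p = 0.806), stromal fibroblasts (1 fall of 16, mean -0.19, adjusted p = 0.285) or leukocytes (1 fall of 14, mean 0.0082, adjusted p = 0.806). The fall in the fibroblast list was TWIST1 (-0.83, adjusted p = 0.0351), lost without control stromal array 2 or 4 or SP stromal array 1, 3 or 4 (adjusted p up to 0.119). The fall in the leukocyte list was CD68 (-0.32, adjusted p = 0.0395), lost without control epithelial array 2, control stromal array 1, 2 or 3 or SP stromal array 1, 2 or 4 (adjusted p up to 0.122). Neither was called adjusted over the list alone.

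Limma called 2704 of 18377 genes in stromal cells (14.7%), 1296 higher and 1408 lower with SP, and 1066 of them changed at least 1.5-fold (469 higher, 597 lower). At an unadjusted p under 0.05 there were 4793. Each single array that was left out kept this count within 1.5 times.

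Whether the cell types respond differently was tested gene by gene as the epithelial minus the stromal response. Medium, growth surface and passage differed with the cell type, so a difference is one between the cell types as grown. Metallothioneins rose in both: the difference for MT1M was 0.51 (adjusted p = 0.66), and for MT1H, which rose more in epithelial cells, it was 1.54 (adjusted p = 0.000766). The stromal rise was larger for SST (difference -4.37, adjusted p = 3.59e-11, epithelial change 0.14), LIF (-3.02, adjusted p = 0.0031), IL1B (-2.91, adjusted p = 0.00749), and HMOX1 (-2.44, adjusted p = 0.00047). It was larger too for ICAM1 (-2.15, adjusted p = 0.00592) and HAS2 (-2.29, adjusted p = 0.026). HAS2 had an epithelial change of 1.56 (adjusted p = 0.123, adjusted p = 0.00175 with the replicate block). The IL1B call was lost without epithelial arrays 1 and 2 (adjusted p = 0.0859). For CXCL8 the difference was -3.35 (adjusted p = 0.024), a call lost without SP epithelial array 1 or 2 or control stromal array 2 (adjusted p up to 0.0522). The chemokine CCL2, with 1.63 ± 0.25 in stromal cells (adjusted p = 0.000581) and -1.15 in epithelial cells (adjusted p = 0.0681), differed by -2.78 (adjusted p = 0.000808). For IL11 (-1.77, adjusted p = 0.329), IL33 (-2.61, adjusted p = 0.164), EDNRB (-2.19, adjusted p = 0.143) and PTGS2 (-1.65, adjusted p = 0.173) the difference was not called. IL11 stood at -1.03, -1.33, -0.52 and -0.18 in control epithelial arrays 1 to 4 and at 0.18, -0.34, 2.64 and 2.96 in the SP epithelial arrays. The stromal falls of DEPP1 (difference 4.12, adjusted p = 0.00139) and LBH (2.27, adjusted p = 0.000238) were larger than the epithelial changes. So were those of KDR (2.29, adjusted p = 0.000664), CITED2 (1.92, adjusted p = 0.000294) and CDKN1B (1.51, adjusted p = 0.00164). In all epithelial arrays KDR lay at -1.02 to -0.13 and CITED2 at -0.85 to -0.27, below every stromal array. Whether KDR and CITED2 could fall in epithelial cells cannot be judged, so their called differences may reflect the baseline rather than the response. Among epithelial calls the difference was called for RIMKLB (2.51, adjusted p = 0.00197), whose stromal change was -0.74 (adjusted p = 0.0753, adjusted p = 0.0334 with the block), and NR4A1 (0.78, adjusted p = 0.027). It was also called for GPR160 (-0.75, adjusted p = 0.0205), ADGRF1 (-0.66, adjusted p = 0.0311) and CX3CL1 (-0.54, adjusted p = 0.0462). It was not called for SMOX (-1.0, adjusted p = 0.0613), CSF3 (1.11, adjusted p = 0.127, stromal change 0.46 with adjusted p = 0.0123 with the block), MAT2A (-0.40, adjusted p = 0.154) or SLC39A10 (0.38, adjusted p = 0.367). In all stromal arrays, with and without SP, GPR160 lay at -1.22 to -1.12, ADGRF1 at -1.96 to -1.68 and CX3CL1 at -1.80 to -1.39. Their lowest control epithelial levels were 1.66, 2.37 and 1.92. Whether these genes were expressed in stromal cells, and so could fall there, cannot be judged. Their called differences may therefore reflect the baseline rather than the response.

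The response differed between cell types for 927 genes by limma, 436 with a positive and 491 with a negative difference (3359 at an unadjusted p under 0.05). The stromal response was the larger for 845 of them and the epithelial for 82. The count was 576 without control stromal array 2, 1416 without control stromal array 1 and 252 without epithelial arrays 1 and 2. In 6 genes both responses were called with opposite signs, against 6.5 for independent lists, so no more than chance gives. Named here after their values were seen, they were AMD1, IL19, NFIL3, PLEKHG2, SLC15A4 and ZBTB38, and for all but ZBTB38 leaving out 1 array could end a call (from 1 such array for SLC15A4 to 10 for AMD1). The cytokine IL19 stood at 1.11 in epithelial cells (adjusted p = 0.00648) and -0.56 in stromal cells (adjusted p = 0.0359), and AMD1, which supplies a building block of polyamines, at -0.56 (adjusted p = 0.0339) and 0.62 (adjusted p = 0.00141). Lists with a called difference were cytokines (mean -1.18, adjusted p = 0.00128, adjusted p = 0.518 with an estimated correlation) and NF-kB targets (-0.70, adjusted p = 1e-08, adjusted p = 0.0661 with an estimated correlation). Interferon (-0.41, adjusted p = 0.0346, adjusted p = 0.904 with an estimated correlation) and heat shock (-0.20, adjusted p = 0.00908, adjusted p = 0.084 with an estimated correlation and 0.062 with the block) were also among them. Without epithelial arrays 1 and 2 the epithelial interferon mean was -0.06, above the stromal -0.19, so that difference changes sign. Mean levels of the cytokine and NF-kB lists were -0.134 and -0.0663 in SP stromal cells, below the 0.587 and 0.265 of control epithelial cells. Differences of these lists may reflect the baseline as well as the response. On the positive side were smooth muscle markers (0.46, adjusted p = 0.00128, adjusted p = 0.142 with an estimated correlation), p53 targets (0.35, adjusted p = 0.00128, adjusted p = 0.306 with an estimated correlation), and metallothioneins (0.32, adjusted p = 0.0346, adjusted p = 0.904 with an estimated correlation and 0.0567 with the block). Mitosis was another (0.25, adjusted p = 0.0346, adjusted p = 0.904 with an estimated correlation). Its epithelial mean was -0.0042 without epithelial arrays 1 and 2 and 0.24 without arrays 3 and 4, against -0.13 in stromal cells. Stromal fibroblast markers had a difference of 0.45 (adjusted p = 0.0567, adjusted p = 0.00284 with the block). The smooth muscle mean lay at -0.672 to -0.149 in epithelial arrays, below the 0.42 to 1.02 of stromal arrays. Room for an epithelial fall of that list cannot be judged.

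Genes higher with SP in both cell types numbered 25, against 4.23 for independent lists (Fisher's exact test, p = 6.07e-14), and genes lower in both numbered 6, against 2.07 (p = 0.0146). The 25 included MT1M, MT1H, MT1F, MT1G, SMOX, NR4A2, IER3 and PRM1. Further genes of the metallothionein family among the 25 were MT1B, MT1DP, MT1E, MT1HL1, MT1IP, MT1JP, MT1P3, MT1X and MT2A. Fisher's test counts members of this family as independent genes, so its p is too small if they respond together. Whether the probe sets of this family tell its members apart was not tested, here or in the counts of the metallothionein list. The 6 were CCNDBP1, CREB3L4, CTC1, MAT2A, NECAP2 and SLC39A10. Some genes of both sets were named only after their values were seen. The lower overlap was 1 to 9 genes with 1 array left out. Its p was over 0.05 without control epithelial array 1 or 2, SP epithelial array 1, 2 or 4 or SP stromal array 3 (up to 0.598). The higher overlap was 20 to 28 (p up to 3.53e-12). Among the 6, only CCNDBP1 kept both calls without each array in turn, and the stromal call of MAT2A (adjusted p = 0.0485) was lost without any 1 of 12 arrays (adjusted p up to 0.149). Of those named among the 25, NR4A2 lost a call without any 1 of 6 arrays, IER3 without any 1 of 5 and MT1DP without any 1 of 4. Across genes, which are not independent replicates, the responses correlated with r = 0.233 (rho = 0.133) over all 18377 genes. Over the 2704 genes called in stromal cells r was 0.384 (rho = 0.259), and over the 87 called in epithelial cells 0.695 (rho = 0.514). Along the axis of the stromal response, with each pair of arrays measured on genes and directions taken from the other 3, the epithelial response was 0.143 ± 0.0228 (SE, n = 4 pairs) of the stromal one. The ratio ran from 0.0852 to 0.192. It matches equal numbers across cell types, where they were not taken to pair, so the SE rests on an arbitrary matching.

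**Figure D2:**
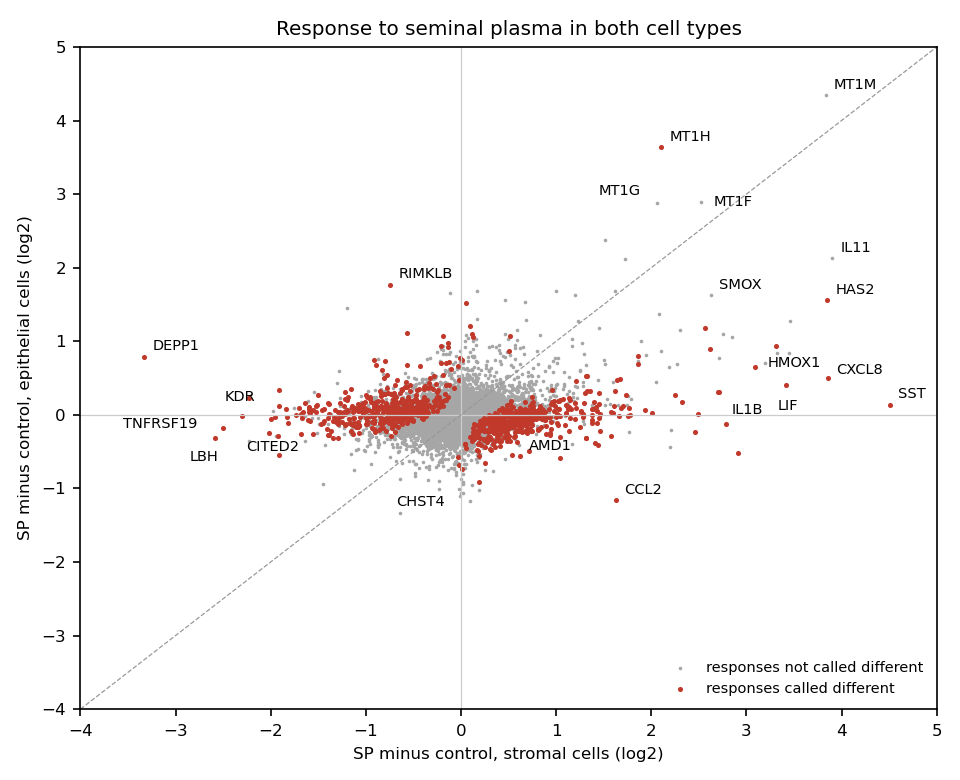
Change with SP in epithelial cells (y axis, log2) against that in stromal cells (x axis, log2), 1 point per gene, with the 927 genes whose responses differed in red. Metallothioneins lie high on both axes, and SST lies high on the stromal axis alone.

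**Figure D3:**
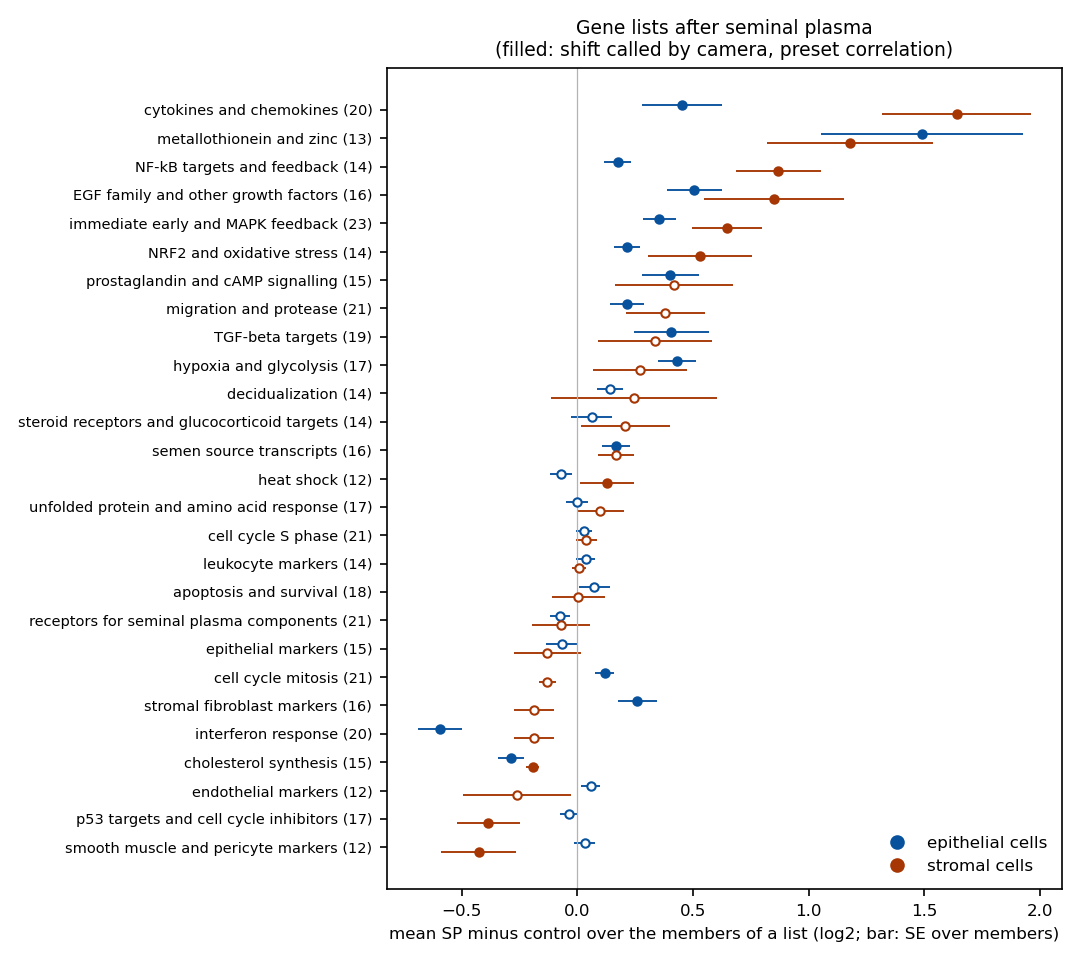
Mean change with SP (log2) of the measured members of 27 gene lists in each cell type, with the standard error over members and filled symbols for lists called by camera with its preset correlation. Cytokines had a mean of 0.45 in epithelial and 1.64 in stromal cells, and metallothioneins 1.49 and 1.18.

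The untreated cell types were compared to describe their baselines. Control epithelial cells had far higher levels of SLPI, a protease inhibitor of mucosal secretions (7.72 ± 0.11, adjusted p = 1.95e-16), and the phosphate transporter SLC34A2 (7.21). Higher too were the acute phase protein SAA1 (7.15), the iron carrier binder LCN2 (7.08), the complement component C3 (7.02) and the chemokine CCL20 (6.91). Control stromal cells had higher levels of the matrix proteins MGP (-6.08 ± 0.15, adjusted p = 1.27e-13), MFAP4 (-5.65) and TGFBI (-4.77), of STMN2 (-5.97), of the cadherin CDH2 (-5.14) and of F2RL2 (-4.75). All 15 measured epithelial markers were higher in epithelial cells (mean 3.88, adjusted p = 1.61e-19, adjusted p = 0.00194 with an estimated correlation), and all 16 stromal fibroblast markers were lower (mean -2.86, adjusted p = 7.42e-10, adjusted p = 0.11 with an estimated correlation). Of 20 cytokines 16 were higher in epithelial cells (mean 2.36, adjusted p = 1.02e-07, adjusted p = 0.104 with an estimated correlation), and so were 16 of 20 interferon genes (mean 1.54, adjusted p = 4.66e-07, adjusted p = 0.26 with an estimated correlation). The same held for 10 of 14 NF-kB targets (mean 1.20, adjusted p = 1.87e-06, adjusted p = 0.0819 with an estimated correlation). Lower in epithelial cells were 13 of 19 TGF-beta targets (mean -1.25, adjusted p = 0.000945, adjusted p = 0.237 with an estimated correlation) and 8 of 12 smooth muscle markers (mean -1.40, adjusted p = 8.39e-05, adjusted p = 0.0819 with an estimated correlation). Of 21 mitotic genes 13 were higher in epithelial cells and 1 lower (mean 0.51, adjusted p = 0.00168, adjusted p = 0.501 with an estimated correlation). Limma called 7153 genes (38.9%), 3430 higher and 3723 lower in epithelial cells. The cell types differed in medium, growth surface and passage as well, so these values compare cultures as grown.

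Transcripts of sperm, prostate and seminal vesicle were examined because cells of the endometrium should hardly make them. PRM1, a protamine that packs sperm DNA, rose by 0.82 ± 0.11 in epithelial cells (adjusted p = 0.00241) and by 0.66 ± 0.11 in stromal cells (adjusted p = 0.000969), higher in 4 of 4 pairs in each. The epithelial call was lost without arrays 3 and 4 (adjusted p = 0.0538) or arrays 1 and 2 (adjusted p = 0.0824), where the change was 0.81 and 0.84. PRM2 stood at 0.54 (adjusted p = 0.127) and 0.31 (adjusted p = 0.164), and MSMB, a prostate secretory protein, at 0.34 (adjusted p = 0.306) and 0.31 (adjusted p = 0.0948). Of 16 members 1 rose in epithelial cells (4 adjusted over the list alone), with a mean of 0.17 (adjusted p = 2.37e-05, adjusted p = 0.0238 with an estimated correlation). In stromal cells 1 rose and 1 fell (SPATA18, -0.48, adjusted p = 0.0347, lost without control stromal array 2, 3 or 4 or SP stromal array 1 or 2, adjusted p up to 0.116). The stromal mean was 0.17 (adjusted p = 0.0543, adjusted p = 0.0441 with the replicate block), and the list was called without any 1 of SP epithelial arrays 2, 3 and 4, control stromal array 1 and SP stromal array 3 (adjusted p down to 0.0265). Control stromal array 1 had a list mean of 0.06, against -0.11 to -0.10 in the other control stromal arrays.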

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

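The tests of whether control stromal array 1 has an additive baseline or RNA of SP-treated cells mixed in, and both tests of stromal cells in epithelial arrays 3 and 4, were chosen only after the results were seen. The tests of a swap, of contact with SP (together with RNA of SP-treated cells), of RNA carried over with SP and of other splits of the arrays were planned before.

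Epithelial arrays 3 and 4 carried more stromal transcripts than arrays 1 and 2, and the pattern reached the SP response. In control arrays 1 to 4, GREM1 stood at 4.99%, 3.52%, 28.7% and 32.2% of its control stromal level and DCN at 19.5%, 8.9%, 72.7% and 84.5%, and the SP rise of IL11 was 5.7%, 3.47%, 49.1% and 61.2% of the stromal rise in pairs 1 to 4. Stromal cells in the state of the stromal cultures would raise all stromal genes by a like percentage, and this is argued against: of the 20 genes lowest in control arrays 1 and 2, 7 had an excess in both arrays 3 and 4 under 0.5 times the median excess of 4.96%, and 5 had over 2 times it. MGP, the most stromal transcript, stood at 1.49%, 1.42%, 1.82% and 1.24%, and the SP rise of SST was 0.157%, 0.0112%, 0.529% and 0.826% of the stromal rise. Stromal cells in another state may still be present. The median excess of 4.96% (range -0.0789% to 27.3%) cannot decide this. Its genes were picked as lowest in arrays 1 and 2, which by itself favours an excess in arrays 3 and 4. Over the 16 stromal fibroblast markers, which were not picked that way but showed the pattern first, the median excess was 7.03% (range -6.92% to 64.4%). Because no biological explanation was tested, a difference between donors or cultures stays open as well.

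Control stromal array 1 lay between the other controls and the SP arrays, at 0.458 on an axis from 0 (other controls) to 1 (SP) over 1345 genes, where the other controls lay at -0.0991, 0.136 and -0.0618. A swap with an SP array is argued against, since the lowest SP stromal array lay at 0.953. So is a baseline that adds to the response, since SP stromal array 1 deviated only 0.0369 ± 0.0177 times as far as control stromal array 1. That ratio covers 1158 genes called without these 2 arrays and rests on 1 pair. In this paragraph ± is the standard error over genes, which are not independent replicates. RNA of SP-treated cells mixed in is argued against by direction: 567 rising genes lay at 0.435 ± 0.0137 and 778 falling genes at 0.467 ± 0.0138, where a share of 44.5% would give 0.518 and 0.378. The falling minus the rising position was 0.0317, against -0.141 for mixed-in RNA of cells like those on the SP arrays and -0.0585 to 0.0415 on the other 3 controls. Contact with a smaller amount of SP is neither shown nor excluded. The 7 metallothionein genes lay at 0.313 ± 0.11, not below the 0.458 by more than 2 standard errors. The semen list mean on this array was 0.0559 against -0.113 to -0.0974 on the other controls. The position differed between lists and genes. NF-kB targets, at 0.152 ± 0.0584, and 3 NRF2 genes, at 0.0255 ± 0.106, lay below the 0.458 by more than 2 standard errors. Migration genes lay at 0.741 ± 0.172. SST stood at 0.089, within the other controls (-0.05 to 0.202) and far from the SP arrays (4.418 to 4.842). IL33 stood at 2.692, above the other controls (-0.697 to 0.738). No biological explanation was tested, so a different state of this culture stays open too.

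The semen transcripts were higher with SP in epithelial cells, and PRM1 rose in both cell types. RNA carried over with the seminal plasma may be the source, but the test leaves it open. Over 10 abundant semen transcripts the median change was 0.178 ± 0.0831 in epithelial and 0.213 ± 0.0917 in stromal cells (± is the SE of the mean over members). The bound set beforehand for carried-over RNA was a median over 0.2 in both cell types. It was not met, and neither median lay more than 2 standard errors below it. KLK3 and SEMG1, which are abundant in prostate and seminal vesicle, stood at 0.11 and 0.18 in epithelial and 0.08 and 0.17 in stromal cells. Induction of PRM1 by the cells was not tested.

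Chance was weighed by splitting the arrays in other ways. Of the 35 splits of the 8 epithelial arrays, 2 called at least as many genes as the real one (87), so chance is not excluded at 0.05. The highest other split, arrays 1 and 2 against 3 and 4, called 802, several times the real count, which points to a structure of the arrays other than treatment. It keeps the same-numbered pairs together, whereas among the 8 splits that part all 4 pairs, the real one included, the highest other called 2. At 1.5-fold, 2 of the 35 splits reached the real 55, and the highest other called 451 (2 among those that part all pairs). For stromal cells 1 of the 35 splits, the real one, called 2704 (highest other 172). At 1.5-fold 1 of the 35 called 1066 (highest other 86). Both are shares under 0.05 when the pairs are ignored. Of these 35 splits, 8, the real one included, part all 4 pairs (highest other 1, and 1 at 1.5-fold). In either cell type 8 are too few for a share under 0.05, so with the pairs kept these splits cannot exclude chance. For the control cell types 1 of the 35 called 7153 (highest other 0, with limma), again a share under 0.05. Every other split mixes the cell types and puts their difference into the spread, so the 0 adds little. For the difference of responses 1 of 100 drawn relabellings called 927 (highest other 293), also a share under 0.05. The relabellings were drawn without regard to pairs, and none that keeps the pairs was run.

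Single arrays far from the other 3 of their group, by a gap beyond Dixon's critical value for groups of 4, turned up in 24 of 560 groups for named genes and 6 of 108 for lists, while chance gives about 1 in 20 groups. Control stromal array 1 stood out for MT1E (-0.426, others -1.46 to -1.35), NR3C1 (-0.124, others -0.973 to -0.868) and TEK (1.12, others 2.21 to 2.39), in each case toward the SP arrays. Control epithelial arrays stood out for CLMN (array 1, 1.05), TLR4 (array 2, 0.131), and TAGLN (array 2, -1.78). Others were MAT2A (array 3, 0.0738), ADGRF1 (array 4, 2.81), CCL20 (array 4, 3.27) and NDRG1 (array 4, 0.504). SP epithelial arrays stood out for CITED2 (array 1, -0.789), KLF9 (array 1, 0.254), TGFBR3 (array 2, 0.29), ADGRF1 (array 3, 2.18) and CCL2 (array 4, -0.159). In control stromal array 4 it was HMOX1 (-0.948). SP stromal arrays stood out for EDNRB (array 1, 3.14), ANGPTL4 (array 1, 1.75), ITGA2 (array 1, 1.98), TAGLN (array 2, 1.05), LDHA (array 2, -0.0667), NRG1 (array 3, 1.97), SLC34A2 (array 3, -3.7) and SDF2L1 (array 4, 1.09). List means stood out for apoptosis (-0.129) and interferon (-0.728) in SP stromal array 3, heat shock (0.159) in SP epithelial array 4, leukocyte markers (0.21) in control epithelial array 4, endothelial markers (0.376) in control stromal array 3 and semen transcripts (0.0559) in control stromal array 1.

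The tested difference between the responses of the cell types, epithelial minus stromal, was called for 927 genes, among them 57 named ones, and for 8 lists. With an estimated correlation it was called for 0 of the 27 lists, and by fry for 6. The largest negative differences, where the stromal change was the more positive, were those of SST (-4.37), CST1 (-3.44), CXCL8 (-3.35), LIF (-3.02), IL1B (-2.91), CCL2 (-2.78), HMOX1 (-2.44), IL7R (-2.37), HAS2 (-2.29) and ICAM1 (-2.15). For CST1 (adjusted p = 0.0454) the call was lost without any 1 of 13 arrays, all but control epithelial arrays 3 and 4 and control stromal array 1 (adjusted p up to 0.0944). Smaller ones were IL1R1 (-1.85), EGR3 (-1.45), NR3C1 (-1.44), NR4A2 (-1.38), SPRY2 (-1.37), NFKBIA (-1.3), REL (-1.18), VEGFA (-1.17), ITGB3 (-1.11), CYP1A1 (-1.1), PFKFB4 (-1.06) and GCLM (-1.0). Below 1 in size were KLF10 (-0.95), LDHA (-0.84), SDF2L1 (-0.79), TNFAIP3 (-0.79), GPR160 (-0.75), HSPD1 (-0.71), ADGRF1 (-0.66), BIRC2 (-0.63), MCL1 (-0.62), HSPE1 (-0.60), DNAJA1 (-0.55) and CX3CL1 (-0.54). GPR160, ADGRF1, CX3CL1 and CYP1A1 lay below all their control epithelial levels in every stromal array, so room for a fall there cannot be judged. IL1B, IL1R1, NFKBIA, TNFAIP3 and LDHA stayed lower in every SP stromal array than in any control epithelial array. Their differences may reflect the baseline as well as the response. Positive differences were those of DEPP1 (4.12), RIMKLB (2.51), STMN2 (2.45), TNFRSF19 (2.33), KDR (2.29), LBH (2.27), KRT19 (1.94), CITED2 (1.92), TEK (1.81), ETV1 (1.77), AKAP12 (1.66), TP53INP1 (1.64), MT1H (1.54), CNN1 (1.54), CDKN1B (1.51), CCN1 (1.44) and BMF (1.1). For TNFRSF19 the call was lost without control stromal array 2 or SP stromal array 1 (adjusted p up to 0.0548). Below 1 were KIF23 (0.96), ELF3 (0.85), NR4A1 (0.78), ZMAT3 (0.73), BCL2L1 (0.66) and KLF9 (0.47). KDR, CITED2, STMN2, TEK and CNN1 lay lower in every epithelial array than in any stromal array, so room for an epithelial fall cannot be judged. The lists were cytokines (-1.18), NF-kB targets (-0.695), interferon (-0.406), heat shock (-0.199), mitosis (0.249), metallothioneins (0.315), p53 targets (0.349) and smooth muscle markers (0.459). Without epithelial arrays 1 and 2 the epithelial means of interferon and mitosis were -0.06 and -0.0042, against -0.19 and -0.13 in stromal cells.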

How the results depend on the processing

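Fits without both stromal arrays numbered 1, and without epithelial arrays 3 and 4 or 1 and 2, were added after seeing the data. The epithelial count (87) was 137 with the replicate block within cell type, 36 with only the 8 epithelial arrays, 228 without arrays 3 and 4, 46 without arrays 1 and 2 and 30 at an adjusted p under 0.01. Leaving out 1 array gave 49 to 97 (49 without control epithelial array 2 and without SP epithelial array 1, 51 without control epithelial array 3). At 1.5-fold (55) it was 24 with only the 8 arrays, 182 without arrays 3 and 4 and 24 at 0.01, and 35 (without control epithelial array 2) to 60 with 1 array left out. The stromal count (2704) was 1415 at 0.01, and 1909 to 3121 with 1 array left out. The count of differing responses (927) was 252 without epithelial arrays 1 and 2, 267 at 0.01, and 576 (without control stromal array 2) to 1416 (without control stromal array 1). The overlap (31) was 60 with the block, 20 with only 8 arrays and 16 without epithelial arrays 1 and 2. Fewer arrays or a stricter threshold enter by construction in most of these fits. For the block and the gain without epithelial arrays 3 and 4 the cause was not tested. Called lists in epithelial cells (15) numbered 4 with an estimated correlation and 6 by fry, and in stromal cells (10) 1 with an estimated correlation and 14 by fry.

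The semen list in stromal cells (mean 0.168, adjusted p = 0.0543) passed 0.05 with arrays centred (0.158), array weights (0.186) and both stromal arrays 1 left out (0.198). It also passed, at the same mean of 0.168, with both blocks, fry and either pair of epithelial arrays left out. The mean was 0.146 to 0.209 with 1 array left out, and adjusted p over all alternatives with 1 array left out was 0.0265 to 0.0982. In 2 cases a shift turned: stromal fibroblast markers in epithelial cells to -0.033 after quantile normalization, and hypoxia and glycolysis in epithelial cells, whose mean was 0.00281 without arrays 1 and 2 while its test pointed down. The cause was not tested. Of 141 calls of named genes 96 held under every alternative, 45 were lost in at least 1 and 0 turned, and 9 of 22 uncalled results were gained in at least 1. With the block within cell type, adjusted p was 0.00315 for TGFBI, 0.00485 for PTGS2, 0.0215 for REL and 0.0496 for PFKFB4 in epithelial cells and 0.0366 for C3 and 0.00386 for CDH2 in stromal cells, none of them called without it, while ABCC2 in stromal cells (0.0282) was lost (0.0594). Apart from these and the calls given with a blocked value in the results, it changed no other call of a named gene or list. Filters at the 25th percentile and the median of brightness were not run, because centring had removed the brightness that signal over background would be judged by.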

Other observations

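All genes of the first paragraph except SST, KDR, TEK and EGFR were chosen after their values were seen. The test of polyamine genes was planned before its 10 genes were looked at.

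Several genes of neuropeptides and of the secretory granules that hold them rose with SP in stromal fibroblasts beside SST. CGA, the subunit shared by the glycoprotein hormones, rose by 2.49 ± 0.27 (n = 4 arrays per group, limma adjusted p = 4.85e-05), the tachykinin precursor TAC1 by 2.25 ± 0.27 (9.26e-05), the galanin gene GAL by 1.76 ± 0.21 (8.24e-05) and the enkephalin precursor PENK by 1.66 ± 0.17 (2.85e-05). Of the granins, SCG2 rose by 1.39 ± 0.12 (6.69e-06), CHGB by 0.81 ± 0.09 (7.02e-05) and VGF by 0.68 ± 0.14 (0.0036). The difference from the epithelial response was called for CGA (-2.48, 0.00277), TAC1 (-1.98, 0.00922), GAL (-1.67, 0.00592), PENK (-1.69, 0.00165), SCG2 (-1.31, 0.000808) and CHGB (-0.76, 0.00564), not for VGF (-0.57, 0.112). Not called were CRH (0.07, 0.348) and NTS (0.02, 0.904), and whether their transcripts were detected cannot be judged. Neither peptide genes nor receptor tyrosine kinases were tested as a list. Among single receptor genes, KDR stood at -2.30 ± 0.20 (6.69e-06), KIT, the stem cell factor receptor, at -1.76 ± 0.38 (0.00577) and TEK, the angiopoietin receptor, at -1.64 (0.000138), ERBB2 at -0.50 (0.0141) and EGFR at 0.97 ± 0.26 (0.0212). The call of EGFR was lost without control stromal array 2 or 4 or SP stromal array 1 or 4 (adjusted p up to 0.073), and the difference from the epithelial response was not called for KIT (1.85, 0.0636), ERBB2 (0.44, 0.186) or EGFR (-1.06, 0.125).

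In epithelial cells SMOX (1.63) and ODC1 (0.90) were higher and AMD1 (-0.56) and MAT2A (-0.74) lower with SP, genes that act in polyamine turnover, and semen is rich in spermine. The call of ODC1 was lost without control epithelial array 3 or SP epithelial array 1 (adjusted p up to 0.0583). That of AMD1 was lost without any 1 of 10 arrays, among them all epithelial ones but SP array 2 (adjusted p up to 0.107). SMOX and MAT2A were not called without epithelial arrays 1 and 2 (adjusted p 0.0824 and 0.241). The hypothesis that this may be a response to a polyamine load was tested on 10 other genes of the pathway. In the predicted direction moved 5 of 10 in epithelial cells and 4 of 10 in stromal cells. By the bound set beforehand, 5 or fewer in either cell type, the hypothesis failed. Only after the result was seen was that bound found faulty, because it counted directions whether or not a gene had changed. In epithelial cells limma called 0 of the 10 (adjusted p 0.788 to 0.972, and 0 at an unadjusted p under 0.05). There the test therefore decides nothing, and the hypothesis stays open. In stromal cells 5 of the 10 were called, in both directions, so they do not favour the hypothesis. With the prediction went SAT1, which acetylates polyamines (0.95, 0.00389), and AZIN1 (-0.38, 0.00309). Against it went the spermidine synthase SRM (1.02, 0.000465), MTAP (0.63, 0.000873) and OAZ2 (-0.24, 0.044), whose call was lost without any 1 of 11 arrays, all but control epithelial arrays 2 and 4, SP epithelial array 4, control stromal array 1 and SP stromal array 3 (adjusted p up to 0.141). The genes that prompted the hypothesis do not all go with it either. ODC1, the first enzyme of synthesis, was higher in both cell types (0.90 and 0.62, the latter at adjusted p = 0.0142 and 0.0513 without control stromal array 2), and AMD1 was higher in stromal cells (0.62, 0.00141), while a load would lower synthesis genes.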
